A study of Homo sapiens with 82 samples.

How the data were processed

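RNA from 7 established breast cancer cell lines was sequenced after 24 h of treatment with DMSO, 1 nM E2 or 1 µM of another ligand, with 2 libraries in each of 41 groups of line and ligand, 82 libraries in all. GDC-0927 and GNE-274 were given to 3 of the lines. The deposited table holds raw read counts of the authors for 30727 genes with Entrez IDs and 1 column per library, on the GRCh38 build according to the processing notes of the authors. The aligner, the counting program and the use of strand are not given in the sources used here. The extraction protocol names a pair of library kits without saying which library came from which. The columns were matched to the labels by title, and cell line and treatment in the file header matched for 82 and 76 libraries. The other 6 are the GNE-274 libraries, which the header lists under another compound code. Gene symbols that a spreadsheet had turned into dates (28) and 29 of 135 empty symbols were restored from RefSeq by Entrez ID.

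Total counts were 15.9 to 55.2 M per library. For statements across lines the duplicates of each group were summed, so that the cell line was the unit of replication. Sums were normalized by TMM, filtered with filterByExpr and tested with edgeR 4.0.16 quasi-likelihood F-tests in R 4.3.3, with line and ligand as factors. One fit held DMSO and the 4 ligands given to all 7 lines (35 sums, 24 residual degrees of freedom) and the other all ligands in MCF-7, HCC1500 and CAMA-1 (21 sums, 12 residual degrees of freedom). Within each line, single libraries of all ligands shared 1 estimate of the spread, in 34 comparisons with DMSO and 3 of GDC-0927 with GNE-274. Whether an effect differed between lines was tested by an F-test of the line by ligand interaction with 6 degrees of freedom on 28 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each comparison. Fold changes are given on the log2 scale with the standard error and the 95% interval of the fit.

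The 16 gene lists, with 295 genes that were all found in the table, were written from general knowledge of the pathways. They cover estrogen-induced, estrogen-repressed, DNA replication, mitosis, cell cycle exit, cholesterol synthesis, unfolded protein response, aryl hydrocarbon receptor target, oxidative stress, interferon-stimulated, luminal lineage, basal and mesenchymal, blood cell, glucocorticoid and progesterone receptor target, ribosome biogenesis and histone genes. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, and members were counted after adjustment over all genes and over the list alone. The score of a list in a line is the mean over its members of the log2 CPM (prior count 2) with the ligand minus DMSO, tested over lines by an exact 2-sided sign-flip permutation. Similarity to the E2 response was the correlation across genes of log2 changes, with E2 set against DMSO replicate 1 and the other ligand against DMSO replicate 2. The labels give no replicate numbers, and replicates were numbered in the order of deposition.

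Lists, the tests of the comparisons, alternatives and the rule for naming genes were fixed before the data were examined, and the tests of possible explanations were chosen afterwards. Named genes are the up to 10 largest rises and 10 largest falls among genes called with the same sign in every line and an average log2 CPM of at least 1, up to 2 members per direction of each list, and ESR1, PGR, GREB1, TFF1, MYC, CCND1, MKI67 and CYP1A1. Alternatives were DESeq2 1.42.0 (its size factors in edgeR, its Wald test and its likelihood ratio test), no filter, a fit of only the 2 groups compared, single libraries in place of sums, a prior count of 0.5, and leaving out each line or library. The count of genes called in the same direction within each of 3 lines and the fits without 3 libraries with a high mitochondrial share were added after the data were seen.

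The tests were tried on simulated counts with the means, library sizes and spread of the data and 200 genes changed by known amounts. Over 7 lines edgeR recovered 53.7%, 86.6% and 97.0% of genes changed by 0.5, 1 and 2 log2 units, and 16 of 174 calls were false. Over 3 lines it recovered 16.4%, 68.7% and 92.4%, with 10 of 128 calls false. Within MCF-7 the shares were 62.7%, 74.6% and 87.9%, and within T-47D 22.4%, 77.6% and 97.0%. The interaction test recovered 16.4%, 59.7% and 66.7% of changes placed in a single line. Of its 107 calls 12 were false (11.2%), and DESeq2 had 20 false of 179 calls (11.2%) over 7 lines and 26 of 157 (16.6%) over 3 lines, so all of these exceed the nominal 5%, as do the 9.2% and 7.81% of edgeR over 7 and 3 lines. No library was left out of the comparisons as a default.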

Results

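RNA sequencing counts for 30727 genes were available from 82 libraries of 7 established breast cancer cell lines that express the estrogen receptor: MCF-7, HCC1500, MDA-MB-330, EFM-19, T-47D, BT-474 and CAMA-1. The cells had been held in hormone-deprived medium for at least 3 days and then treated for 24 h. All 7 lines received DMSO, 1 nM estradiol (E2), or 1 µM of 4-OH tamoxifen, GDC-0810 or Fulvestrant. MCF-7, HCC1500 and CAMA-1 also received 1 µM GDC-0927 or GNE-274. E2 is the natural agonist of the receptor, 4-OH tamoxifen is the active metabolite of tamoxifen and a partial agonist, Fulvestrant is an antagonist that leads to receptor degradation, and GDC-0810 (brilanestrant) was developed as an oral degrader. GDC-0927 and GNE-274 are known here by code name alone. Each of the 41 groups of line and ligand had 2 libraries, and 0 other libraries were left over. The comparisons ask how far each ligand moves expression from the vehicle state, in which direction relative to E2, and whether the lines respond alike.

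Total counts per library ranged from 15.9 M to 55.2 M, with a median of 23.4 M. CAMA-1 was the deepest line, with 42.0 to 55.2 M. The library titles carry running numbers that form 5 blocks, and the GDC-0927 and GNE-274 libraries of MCF-7 and HCC1500 lie in another block than the DMSO libraries of these lines. In MCF-7 the later block held 39.8 to 43.0 M counts per library and the earlier one 15.9 to 25.1 M. In HCC1500 the ranges were 21.7 to 27.3 and 17.5 to 23.7 M. All CAMA-1 libraries lie in 1 block. Each of the 82 libraries was nearest to a library of its own line, and 66 were nearest to their own duplicate. The duplicates differed by more than counting error, with a chi-square per degree of freedom from 1.39 to 44.3, highest in T-47D with Fulvestrant. The share of mitochondrial counts reached 18.6% in BT-474, where it was 6.18% or more in every library, and stood apart from its duplicate in 1 library each of EFM-19 with 4-OH tamoxifen (8.37%), T-47D with DMSO and T-47D with Fulvestrant (10.9%). Duplicates in BT-474 stood as far apart, at 6.18% and 10.7% with GDC-0810, where the chi-square per degree of freedom was 43.7, and at 9.24% and 13.6% with E2.

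E2 raised the classic targets of the receptor in every line. TFF1, a secreted trefoil peptide, rose by 4.26 ± 0.42 log2 units (SE, n = 7 lines), 19.2-fold. GREB1, a cofactor of the receptor, rose by 3.41 ± 0.44, and PGR, the progesterone receptor, by 3.15 ± 0.42. The scaffold protein gene PDZK1 rose by 4.41 ± 0.47, the chemokine gene CXCL12 by 3.67 ± 0.50, the transcription factor gene EGR3 by 3.61 ± 0.30, and the noncoding RNA LINC01016 by 4.72 ± 0.42, the largest rise among genes changed in the same direction in all 7 lines. MAT1A, which encodes a methionine adenosyltransferase, rose by 3.74 and PGLYRP2, a peptidoglycan recognition protein, by 4.02. PGLYRP2 had 0 to 1 counts in the BT-474 DMSO libraries and 4 to 5 in those of MCF-7. The steepest decreases in all 7 lines were in ATP13A5 (log2 change −2.23), HOPX (−2.18) and PSCA (−2.17), followed by BCAS1 (−1.82), the interleukin receptor gene IL1R1 (−1.79) and TP53INP1 (−1.71). The receptor's own transcript, ESR1, did not pass the test (log2 change −0.06, 95% interval −0.41 to 0.28, adjusted p = 0.77). Its change differed between lines (F-test of the interaction, adjusted p = 3.7e-16). ESR1 was higher with E2 in EFM-19 (438 CPM against 245 with DMSO) and MDA-MB-330 (367 against 268). It was lower in the other lines, for example MCF-7 (344 against 480).

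Of the 18445 genes tested over 7 lines, 9352 passed an adjusted p of 0.05 with E2, 4176 higher and 5176 lower, and 4775 of them had the same sign in every line. Changes of at least 1 log2 unit were seen in 727 genes upward and 554 downward. Of the 45 genes of the estrogen-induced list, 43 rose, with the same 43 when adjusted over the list alone, and 8 of 9 estrogen-repressed genes fell, also 8 adjusted over the list alone. Both lists passed a set test with an estimated correlation (adjusted p = 0.00108 and 0.0343).

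Genes of cell division rose with E2 as well. All 30 DNA replication genes rose, with RRM2, a subunit of ribonucleotide reductase, at 2.01 and MCM10 at 1.99 log2 units, as did all 26 mitosis genes, with the kinases AURKB at 1.80 and CDK1 at 1.72. These counts were 30 and 26 adjusted over each list alone, and the set tests gave adjusted p = 0.262 and 0.358 with an estimated correlation. MKI67, a proliferation marker, rose by 1.71 ± 0.38, MYC by 2.28 ± 0.39 and the cyclin gene CCND1 by 0.73 ± 0.14, the last in 6 of 7 lines. Of 20 ribosome biogenesis genes 19 rose (20 adjusted over the list alone), for example NOP56 by 0.86 and FBL by 0.68, with adjusted p = 0.214 with an estimated correlation. Among 12 genes of cell cycle exit, BTG2 (−1.10), CDKN2B (−0.73), FOXO3 (−0.36) and RBL2 (−0.24) fell and CDKN2C rose (1.46), and these counts were the same adjusted over the list alone.

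Other lists moved less uniformly with E2. Of 24 cholesterol synthesis genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation), among them ACAT2 (0.86) and EBP (0.74). Of 15 interferon-stimulated genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.451 with an estimated correlation), among them IFI44L (−1.63) and OAS2 (−1.17). With DMSO and E2, IFI44L had 0 counts in EFM-19 and BT-474 and at most 2 per library in T-47D and CAMA-1. OAS2 had at most 5 in EFM-19, BT-474 and CAMA-1. Replication-dependent histone genes fell in 10 of 11 cases (10 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), for example HIST1H2AC by −1.01. Luminal lineage genes fell in 10 of 17 cases and rose in 2, as they did adjusted over the list alone (adjusted p = 0.358 with an estimated correlation), with KRT7 at −0.71 and TFAP2C at 0.85. In the unfolded protein response list 10 of 17 genes rose and 3 fell (adjusted p = 0.373 with an estimated correlation), and in the oxidative stress list 5 of 12 rose, OSGIN1 by 1.42, and 1 fell. Among the 6 aryl hydrocarbon receptor targets 2 rose, TIPARP (0.89) and CYP1B1 (0.76), and 2 fell, CYP1A1 (−1.35 ± 0.22) and CYP1A2 (−1.73). Of 9 tested targets of the glucocorticoid and progesterone receptors 3 rose, SGK1 (1.84), MT2A (0.81) and FKBP5 (0.68), and 3 fell, TSC22D3 (−0.80), KLF9 (−0.72) and DUSP1 (−0.69). Of 14 tested basal and mesenchymal markers 1 rose, VIM (0.46), and 2 fell, COL3A1 (−0.58) and COL1A1 (−0.32). None of 5 tested blood cell markers passed, and their median log2 change was −0.08. For the last 6 lists the counts adjusted over the list alone were the same.

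4-OH tamoxifen raised a small set of genes in all lines. PGLYRP2 rose by 4.73 ± 0.54 log2 units (SE, n = 7 lines), KRT13, a squamous epithelial keratin, by 4.27 ± 0.52, SYNPO2L by 2.81 ± 0.33, LINC01016 by 2.68 ± 0.42 and KIF12, a kinesin gene, by 1.56 ± 0.20. RAPGEFL1 rose by 1.58, the scaffold gene SLC9A3R1 by 1.33, KRT15 by 1.28 and IER3 by 1.16. PPM1K, a mitochondrial phosphatase gene, fell by 0.85 ± 0.13, the growth factor gene TGFA fell by 0.74, MYCN fell by 0.58, and LOC101928673 completed the 4 lower genes. The fold for KRT13 rests on few counts in some lines, with 0 counts in both HCC1500 DMSO libraries and at most 5 counts in the DMSO and 4-OH tamoxifen libraries of BT-474 and CAMA-1. LINC01016 had at most 6 counts in the DMSO libraries of T-47D, BT-474 and CAMA-1. PGLYRP2 had 4 to 5 counts in the MCF-7 DMSO libraries, and in BT-474 0 to 1 with DMSO and 6 to 9 with 4-OH tamoxifen. Against DMSO, 47 genes passed, 43 higher and 4 lower, 34 with the same sign in every line.

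Estrogen-induced and cholesterol synthesis genes moved upward with 4-OH tamoxifen. Of the 45 estrogen-induced genes 4 rose (11 adjusted over the list alone): KRT13, RAPGEFL1, PDZK1 (2.16, 6 of 7 lines) and the amino acid transporter gene SLC7A5 (0.94), and the set test gave adjusted p = 0.0246 with an estimated correlation. Of the 24 cholesterol synthesis genes 1 rose, IDI1 (0.30 ± 0.06), and 13 rose adjusted over the list alone, with adjusted p = 0.00667 with an estimated correlation. The mean log2 change of the cholesterol list was 0.21 with 4-OH tamoxifen and 0.24 with E2. Histone genes had a mean log2 change of −0.21 (adjusted p = 0.199 with an estimated correlation). GREB1 (−0.30), PGR (0.57) and TFF1 (0.69) did not pass over the 7 lines (adjusted p = 1 each). Without HCC1500 the count of genes was 16, without CAMA-1 24, without T-47D 27 and without MDA-MB-330 30. DESeq2 gave 81.

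GDC-0810 left few genes changed over the lines. The 4 genes that passed were all lower: BAMBI, a pseudoreceptor of TGF-beta signaling (−0.55 ± 0.10, SE, n = 7 lines), the kinase gene PRKCD (−0.41 ± 0.08), the phospholipid enzyme gene LPCAT3 (−0.32 ± 0.06; adjusted p = 0.0493 for each) and CLEC3A (−1.94 ± 0.26; adjusted p = 0.0014). BAMBI, PRKCD and LPCAT3 were lower in every line and CLEC3A was not. CLEC3A lies below the expression minimum for named genes and was chosen after its values were seen. Of the 45 estrogen-induced genes 0 passed in edgeR (1 lower adjusted over the list alone), and TFF1 (0.65, interval −0.13 to 1.42), GREB1 (−0.17, −1.01 to 0.66) and MYC (−0.25, −1.02 to 0.52) did not pass. At an unadjusted p under 0.05 there were 985 of 18445 genes. 4-OH tamoxifen had 875 such genes in the same fit and 47 that passed, so this count cannot tell whether further genes changed. DESeq2 gave 13 genes, size factors of DESeq2 in edgeR gave 1, a fit without a filter gave 2, and the fits without EFM-19 or without T-47D gave 0.

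Fulvestrant gave 1 gene below DMSO over the 7 lines, PPM1K (−0.85 ± 0.13, SE, n = 7 lines; adjusted p = 0.0134). Changes that did not pass for single genes had the same sign in all 7 lines for MYC (−0.87, interval −1.65 to −0.10), MKI67 (−0.48, −1.22 to 0.25), GREB1 (−0.74, −1.58 to 0.09), PGR (−0.56, −1.37 to 0.24) and CYP1A1, the aryl hydrocarbon receptor target (0.76, 0.34 to 1.18), each with adjusted p = 1. As sets, estrogen-induced genes were lower (0 of 45 called, 1 adjusted over the list alone; adjusted p = 3.17e-16, and adjusted p = 0.0546 with an estimated correlation). DNA replication (adjusted p = 0.178 with an estimated correlation) and mitosis (adjusted p = 0.309 with an estimated correlation) had mean log2 changes of −0.35 and −0.30. The 6 aryl hydrocarbon receptor targets had a mean log2 change of 0.37 (1 higher adjusted over the list alone; adjusted p = 0.0546 with an estimated correlation). At an unadjusted p under 0.05 there were 381 of 18445 genes. The fit shares the spread of all ligands, and in it 4-OH tamoxifen had 875 such genes and 47 that passed. The count thus cannot tell whether further genes changed. PPM1K no longer passed without MCF-7 (−0.78), T-47D (−0.80), BT-474 (−0.79) or CAMA-1 (−0.82), with 0 genes left without BT-474 and 1 other gene in each of the other fits. A fit of the DMSO and Fulvestrant groups alone, without the spread of the other ligands, gave 284 genes, 76 higher.

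Side by side, GDC-0810 and Fulvestrant differed in 42 genes over the 7 lines. LINC01016 was 2.32 ± 0.52 log2 units higher with GDC-0810 (SE, n = 7 lines), C5AR2, a receptor for complement fragments, 1.80 ± 0.39 higher, KRT16 0.97 ± 0.21 higher and PPM1J 0.96 ± 0.20 higher. The fold for LINC01016 rests on few counts in some lines, with at most 7 per library in MCF-7, T-47D, BT-474 and CAMA-1 with either ligand. BTG2, an antiproliferative gene, was lower by 0.97 ± 0.16 (log2 difference −0.97), and the epithelial transcription factor gene ELF3 (−0.86 ± 0.13), BAMBI (−0.79 ± 0.10), DHRS3, a retinaldehyde reductase gene (−1.31 ± 0.29), and TSC22D3 (−0.65 ± 0.14) were lower as well. In all, 9 genes were higher and 33 lower with GDC-0810, and 35 had the same sign in every line. Of 45 estrogen-induced genes 1 was lower, P2RY2 (−0.45), while 4 were higher and 1 lower adjusted over the list alone (adjusted p = 0.425 with an estimated correlation). TFF1 was 1.06 higher (interval 0.29 to 1.84) with adjusted p = 0.364. The count was 14 without HCC1500 or without BT-474 and 125 by DESeq2.

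4-OH tamoxifen differed from Fulvestrant in 105 genes, 82 higher and 23 lower, 79 with the same sign in every line. PGLYRP2 was 5.20 ± 0.56 log2 units higher (SE, n = 7 lines), LINC01016 4.52 ± 0.49, KRT13 4.49 ± 0.54 and SYNPO2L 2.66 ± 0.33. With Fulvestrant LINC01016 had at most 2 counts per library in MCF-7, T-47D, BT-474 and CAMA-1, and KRT13 at most 4 in HCC1500, MDA-MB-330, T-47D, BT-474 and CAMA-1. PGLYRP2 had 1 to 2 counts in MCF-7, 0 to 1 in BT-474 and 5 to 6 in CAMA-1 with Fulvestrant. CYP1A1 was lower (−1.03 ± 0.21), as were TGFA (−0.82), the transcription factor gene DACH1 (−0.79) and MYCN (−0.63). Of the 45 estrogen-induced genes 11 were higher and 30 were higher adjusted over the list alone, with adjusted p = 0.00148 with an estimated correlation. Of 24 cholesterol synthesis genes 2 were higher, EBP (0.42) and IDI1 (0.29), and 13 adjusted over the list alone, with adjusted p = 0.033 with an estimated correlation. Among the aryl hydrocarbon receptor targets 1 was lower, CYP1A1, and 3 adjusted over the list alone (adjusted p = 0.0996 with an estimated correlation). Without HCC1500 the count was 49 and without T-47D 63.

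GDC-0810 and 4-OH tamoxifen differed in 99 genes, 35 higher with GDC-0810 and 64 lower, 80 with the same sign in every line. KRT13 (−4.54 ± 0.53 log2 units, SE, n = 7 lines), PGLYRP2 (−3.85 ± 0.50), LINC01016 (−2.20 ± 0.39), SYNPO2L (−2.09 ± 0.31) and KIF12 (−1.50 ± 0.19) were lower with GDC-0810. With GDC-0810 KRT13 had at most 4 counts per library in HCC1500, MDA-MB-330, BT-474 and CAMA-1, and LINC01016 at most 7 in MCF-7, T-47D, BT-474 and CAMA-1. PGLYRP2 had 5 counts per library in MCF-7 and 0 to 3 in BT-474 with GDC-0810. The epithelial genes TRIM29 (0.99 ± 0.21) and KRT17, a basal keratin (0.94 ± 0.19), and MYCN (0.73) were higher. Of 24 cholesterol synthesis genes 4 were lower, INSIG1 (−0.39), a regulator of sterol synthesis, DHCR7 (−0.41, 6 of 7 lines), IDI1 (−0.31) and CYP51A1 (−0.26), and 10 were lower adjusted over the list alone (adjusted p = 0.0687 with an estimated correlation). Of 45 estrogen-induced genes 4 were lower, KRT13, TPD52L1 (−1.0), SLC7A5 (−0.80) and P2RY2 (−0.51), and 12 adjusted over the list alone (adjusted p = 0.0687 with an estimated correlation). Of the cell cycle exit genes, TOB1 was lower (−0.47). The count was 32 without BT-474, 35 without EFM-19 and 42 without MCF-7, and DESeq2 gave 280.

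The estrogen-induced score, the mean log2 difference from DMSO over the 45 list genes, placed the ligands in a graded order. It was 1.76 ± 0.30 with E2 (SD, n = 7 lines), 0.43 ± 0.25 with 4-OH tamoxifen, −0.03 ± 0.53 with GDC-0810 and −0.33 ± 0.31 with Fulvestrant. E2 and 4-OH tamoxifen were above DMSO in 7 of 7 lines and Fulvestrant below in 7 of 7, each with p = 0.0156 in an exact 2-sided sign-flip test, the smallest p that 7 lines allow. Over the 16 lists tested, the adjusted p was 0.0312, 0.0832 and 0.0624. Fulvestrant was close to DMSO in MDA-MB-330 (libraries at −0.013 and 0.003) and CAMA-1 (0.001 and −0.034). Its 7 of 7 and the p with it thus depend on the sign of values near 0. As a share of the E2 effect, 4-OH tamoxifen reached 23.7% on average (SD 13.7, n = 7), from 7.9% in MCF-7 to 42% in MDA-MB-330. GDC-0810 ranged from −0.98 in MCF-7 to 0.71 in MDA-MB-330 (exact 2-sided p = 0.922, n = 7 lines), and leaving out MCF-7 turned its mean to 0.13. It exceeded Fulvestrant by 0.30 in 6 of 7 lines (exact p = 0.0469) and lay below 4-OH tamoxifen by 0.46 (difference −0.46) in 7 of 7 (exact p = 0.0156), with adjusted p = 0.0938 and 0.125 over the lists.

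**Figure D1:**
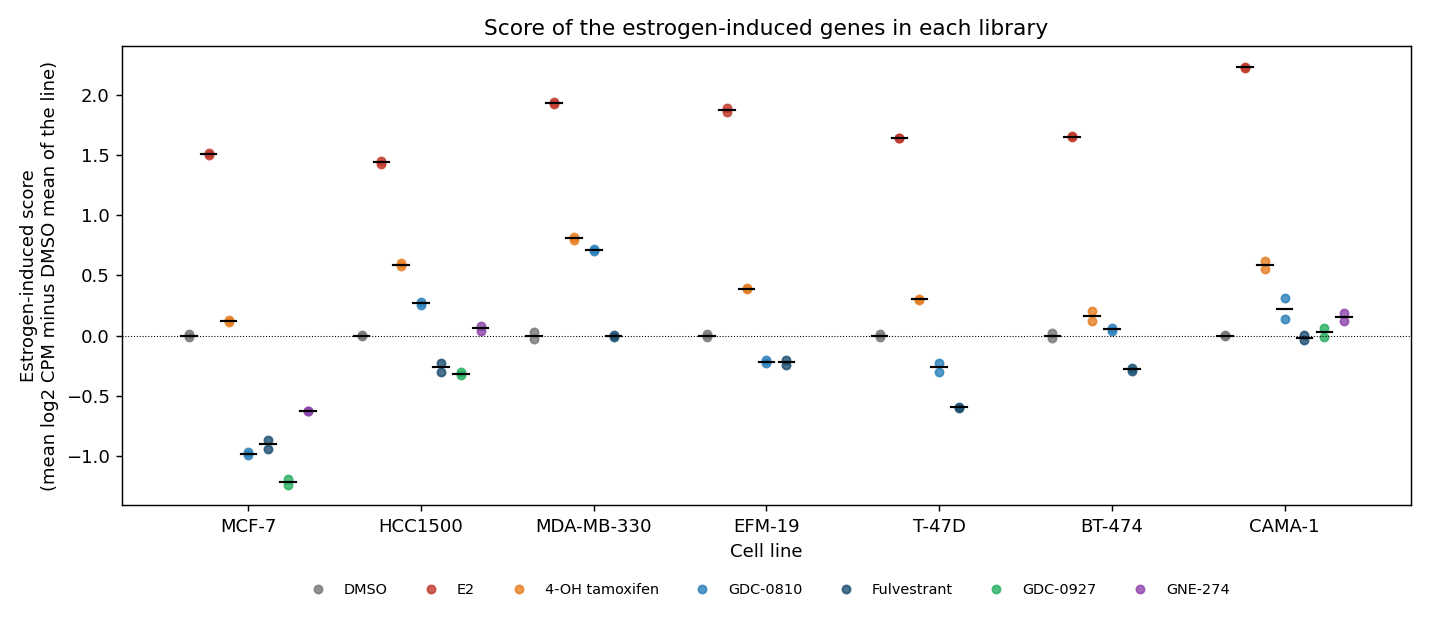
Estrogen-induced score of each library (mean log2 CPM over the 45 list genes minus the DMSO mean of the same line, vertical axis) by cell line (horizontal axis), colored by ligand, with a dot for each library and a bar at the mean of the 2 libraries. E2 libraries lie between 1.42 and 2.23 in all 7 lines, and GDC-0810 libraries run from −0.99 in MCF-7 to 0.72 in MDA-MB-330.

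Across all 18445 tested genes, responses to the ligands were set beside the E2 response with separate DMSO libraries as controls for the 2 sides, since a shared control alone correlates unchanged responses (mean r = 0.50 in 20 simulations). The correlation across genes, which are not independent replicates, was 0.36 for 4-OH tamoxifen, 0.08 for GDC-0810 and −0.45 for Fulvestrant, and 0.02 for simulated unchanged responses. Among 12777 genes with an average log2 CPM of at least 1 it was 0.47, 0.13 and −0.70. By line, 4-OH tamoxifen ranged from 0.02 in BT-474 to 0.57 in CAMA-1, GDC-0810 from −0.28 in MCF-7 to 0.34 in CAMA-1, and Fulvestrant from −0.36 in T-47D to 0.06 in MDA-MB-330. With the DMSO libraries exchanged, T-47D with Fulvestrant was at −0.23, above MCF-7 (−0.33), and BT-474 with 4-OH tamoxifen at 0.08, above T-47D (0.06). The simulated libraries were drawn independently. An effect shared by libraries of the same replicate number would lower r in either arrangement, and its size was not tested.

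Within single lines 4-OH tamoxifen, GDC-0810 and Fulvestrant changed more genes than over the 7 lines together, and some genes moved in opposite directions in different lines. GDC-0810 lowered GREB1 in MCF-7 (−3.02 ± 0.07 log2 units, SE, n = 2 libraries per group) and raised it in MDA-MB-330 (1.07 ± 0.05). It lowered MYC in MCF-7 (−1.57 ± 0.08) and T-47D (−1.27 ± 0.12) and raised it in HCC1500 (0.81 ± 0.07) and MDA-MB-330 (2.23 ± 0.32). With DMSO, MYC was at 0.37 CPM in MDA-MB-330 and 94.0 in MCF-7, so the rise in MDA-MB-330 starts from a low value. TFF1 fell with GDC-0810 in MCF-7 (−0.79 ± 0.06) and rose in MDA-MB-330 (2.57 ± 0.05), HCC1500 (0.71 ± 0.07) and CAMA-1 (1.44 ± 0.14). Fulvestrant lowered GREB1 (−2.87 ± 0.07) and PGR (−1.94 ± 0.15) in MCF-7 and raised CYP1A1 there (1.30 ± 0.17) and in MDA-MB-330 (1.04 ± 0.08). 4-OH tamoxifen lowered GREB1 in MCF-7 (−2.56 ± 0.07) and raised it in MDA-MB-330 (0.70 ± 0.05). E2 raised MKI67 in CAMA-1 (4.70 ± 0.13) and in MCF-7 (0.44 ± 0.05).

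The lists moved with the line as well. GDC-0810 lowered 39 of 45 estrogen-induced genes and 29 of 30 DNA replication genes in MCF-7 (41 and 29 adjusted over the list alone), while it raised 27 of 42 estrogen-induced genes in MDA-MB-330 (27) and all 30 DNA replication genes in HCC1500 (30). Fulvestrant lowered 40 of 45 estrogen-induced genes in MCF-7 (41 adjusted over the list alone) and raised 2 of 42 in MDA-MB-330 (6). 4-OH tamoxifen raised all 30 DNA replication genes in HCC1500 and in CAMA-1 and lowered 3 in MCF-7 (25 adjusted over the list alone). The effect of GDC-0810 differed between the lines in an interaction test for 43 of 45 estrogen-induced genes and all 30 DNA replication genes. That of Fulvestrant differed for 32 and 26, and those of E2 and 4-OH tamoxifen for 45 and 40 estrogen-induced genes.

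Genes called within a line ranged from 4195 in BT-474 to 11693 in CAMA-1 with E2, from 123 in T-47D to 3840 in HCC1500 with 4-OH tamoxifen, from 15 in BT-474 to 3476 in MCF-7 with GDC-0810, and from 16 in MDA-MB-330 to 2243 in MCF-7 with Fulvestrant. Of 13024 genes tested in all 7 lines, E2 raised 600 and lowered 280 in every line, 4-OH tamoxifen raised 6 and lowered 1, and GDC-0810 and Fulvestrant had 0 in edgeR. The effect differed between lines for 11129 of 18963 genes with E2, 3706 of 18837 with 4-OH tamoxifen, 3216 of 18972 with GDC-0810 and 560 of 18846 with Fulvestrant. Without the 3 libraries outside BT-474 with a high mitochondrial share, the counts were 7142 with 4-OH tamoxifen and 1437 with Fulvestrant, and with 1 line left out they ranged from 1937 to 5174 with 4-OH tamoxifen, 1276 to 4251 with GDC-0810 and 217 to 1536 with Fulvestrant. Without a filter they were 5124 with GDC-0810 and 938 with Fulvestrant, and the likelihood ratio test of DESeq2 gave 906 with Fulvestrant. With 1 library left out, E2 in BT-474 gave 2480 to 2706, 4-OH tamoxifen 38 to 185 in T-47D and 2254 to 2611 in HCC1500, GDC-0810 2 to 4546 in BT-474 and 2040 to 2098 in MCF-7, and Fulvestrant 1 to 44 in MDA-MB-330 and 998 to 1153 in MCF-7. Single libraries decided some counts: 4-OH tamoxifen in EFM-19 gave 165 genes, and 6249 when only its library with the high mitochondrial share was kept, and GDC-0810 in BT-474 gave 15, and 4546 without replicate 2. The filter decided others: without it BT-474 gave 1519 genes with GDC-0810, 1584 with 4-OH tamoxifen and 66 with Fulvestrant, MDA-MB-330 162 with Fulvestrant and T-47D 311 with 4-OH tamoxifen. These p-values measure only the spread between the samples of each line.

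**Figure D2:**
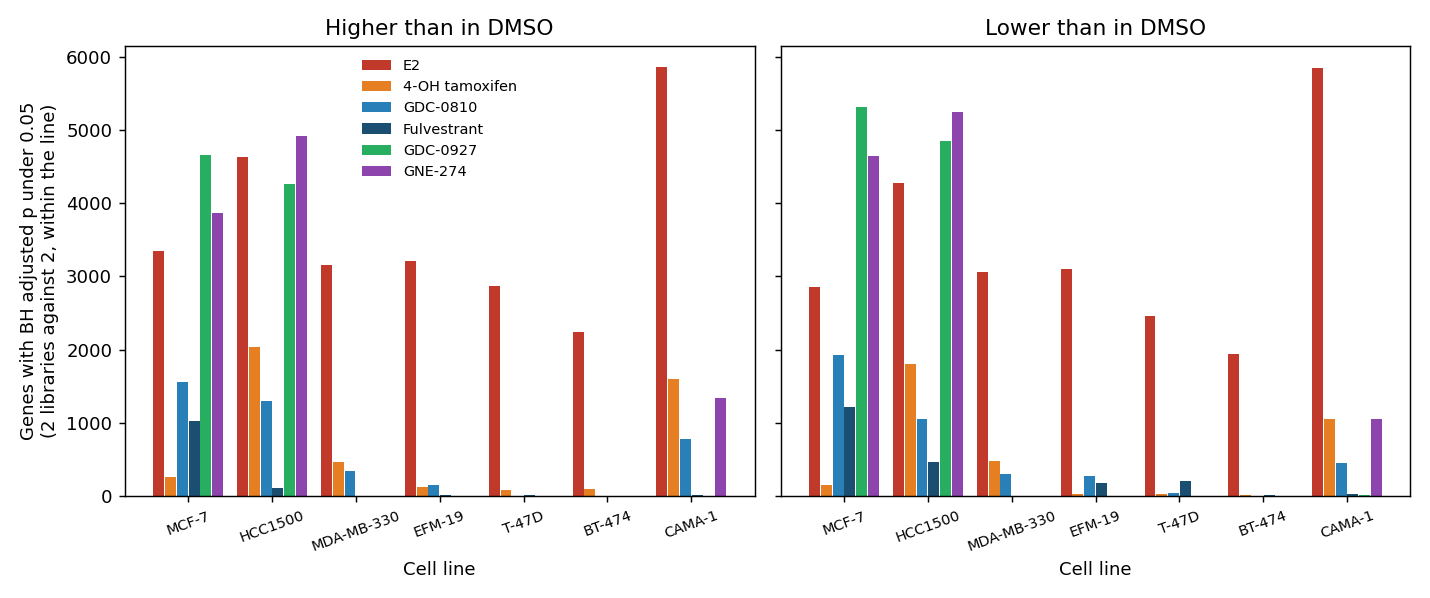
Number of genes with an adjusted p under 0.05 against DMSO within each cell line (vertical axis), with a bar for each ligand and the genes higher (left) and lower (right) in separate panels. E2 gives 2247 higher and 1948 lower genes or more in every line, while GDC-0927 gives 10 and 18 in CAMA-1 and 4659 and 5319 in MCF-7.

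With GDC-0927 and GNE-274, interferon-stimulated genes were far below DMSO in MCF-7 and HCC1500, whose libraries for these ligands lie in another title block than their DMSO. OAS1, an antiviral synthetase gene, was lower by 2.16 ± 0.29 log2 units with GDC-0927 (log2 difference −2.16, SE, n = 3 lines) and by 2.88 ± 0.30 with GNE-274 (−2.88). OAS2 was at −2.93 ± 0.45 and −3.29 ± 0.47, and IFI44L at −4.78 and −5.11. HERC5, which is not in the interferon-stimulated list, was at −2.01 ± 0.32 and −2.27 ± 0.33 and had fewer counts in CAMA-1 as well, 10 to 12 with DMSO, 3 with GDC-0927 and 0 to 4 with GNE-274. It had 24 to 34 counts there with E2 and 3 to 4 with Fulvestrant, so the low counts were not particular to GDC-0927 and GNE-274. Of the 15 interferon-stimulated genes 3 (IFI44L, OAS1 and OAS2) were lower over the 3 lines with either ligand (12 and 13 adjusted over the list alone; adjusted p = 0.824 and 0.494 with an estimated correlation). In CAMA-1 the list members OAS1, OAS2 and IFI44L had at most 5 counts per library with DMSO, GDC-0927 or GNE-274, and 0 of 9 tested members were called with GDC-0927. IFI44L had 305 to 388 counts in the HCC1500 DMSO libraries and 9 to 17 with these ligands, and in MCF-7 it had at most 8 counts with DMSO and at most 1 with these ligands.

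The 6 genes that rose with GNE-274 were PGLYRP2 (4.40 ± 0.73, n = 3 lines), KIF12 (1.93 ± 0.29), STARD10, a lipid transfer gene (0.62 ± 0.10), PLEKHH1, HR and CACNG4, and PGLYRP2, KIF12, STARD10 and PLEKHH1 had risen with 4-OH tamoxifen as well. PPM1K fell with both ligands (−1.28 ± 0.21 with GDC-0927 and −1.31 ± 0.21 with GNE-274). GREB1 did not pass (−1.52, interval −2.78 to −0.27, adjusted p = 0.195 with GDC-0927; −2.97, −4.29 to −1.65, adjusted p = 0.0866 with GNE-274). Over the 3 lines 7 genes passed with GDC-0927, all lower, and 20 with GNE-274, 6 higher and 14 lower, of 18795 tested. Within lines, GDC-0927 changed 9978 genes in MCF-7, 9116 in HCC1500 and 28 in CAMA-1, and GNE-274 changed 8516, 10158 and 2385. The CAMA-1 counts were 2 to 3 with GDC-0927 and 1224 to 1746 with GNE-274 when 1 library was left out, and GDC-0927 gave 119 there without a filter and 50 by DESeq2. CAMA-1 is the one line in which both ligands share a block with DMSO, and without it the 3-line counts rose to 3637 and 2697. Against Fulvestrant, GDC-0927 was lower for 6 genes over the 3 lines and higher for 0, with OAS1 at −2.30 and OAS2 at −2.90, and 8721 genes differed within MCF-7, 9646 within HCC1500 and 59 within CAMA-1.

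In the comparison of GDC-0927 with GNE-274, which share a block and a dose in each line, genes of DNA replication were lower with GDC-0927 within each line, while over the 3 lines their set test gave adjusted p = 0.357 with an estimated correlation and their score exact p = 0.25, the smallest that 3 lines allow (adjusted p = 0.5). CDC45, part of the replicative helicase, was at −0.58 log2 units in MCF-7, −2.00 in HCC1500 and −1.63 in CAMA-1 (n = 2 libraries per group), and RRM2 was at −0.38, −2.12 and −1.49. Of the 30 DNA replication genes 23 were lower in all 3 lines, and of 26 mitosis genes 10, among them MKI67 (−0.18, −1.02 and −0.98). Of 42 estrogen-induced genes 8 were lower in all 3 lines, among them MYC (−0.60, −1.23 and −0.38), NPY1R, a neuropeptide Y receptor gene (−1.98, −0.26 and −1.07), the receptor tyrosine kinase gene RET (−0.46, −1.55 and −0.51) and STC2 (−1.32, −0.78 and −0.30). PGLYRP2 (−3.26, −4.80 and −3.52) and KIF12 (−1.50, −1.57 and −1.97) were lower with GDC-0927 as well. GREB1 went the other way: it was higher with GDC-0927 by 1.42 ± 0.07, 1.16 ± 0.08 and 1.83 ± 0.21. IGFBP4, a binding protein of insulin-like growth factors (1.32, 1.29 and 0.44), was the other estrogen-induced gene that was higher in all 3 lines. The cell cycle inhibitor gene CDKN1A (0.34, 0.15 and 0.13) and BTG2 (0.41, 0.21 and 0.32) were, with BTG1, the 3 of 10 cell cycle exit genes higher with GDC-0927 in all 3.

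GREB1 was lower with GNE-274 than DMSO in MCF-7 (−4.45 ± 0.07), HCC1500 (−1.55 ± 0.08) and CAMA-1 (−1.94 ± 0.21), while with GDC-0927 it was at −0.11 ± 0.16 in CAMA-1 (adjusted p = 0.985). In CAMA-1 GNE-274 raised 26 of 30 DNA replication genes over DMSO (28 adjusted over the list alone) and GDC-0927 raised 0 (0). In total 318 genes were called in the same direction in all 3 lines, 95 higher with GDC-0927 and 223 lower, of 14473 tested in all 3, where independent calls would give 16.5. These counts rest on the calls within each line, which with 1 library left out ran from 716 to 4900 in MCF-7, where all libraries gave 2555, and from 857 to 1222 in CAMA-1, where they gave 1786. Of the 223, E2 had raised 207 and lowered 3 in the 7-line comparison, and of the 95 it had lowered 67 and raised 10. The genes named from this set were chosen after their values were seen. Of 18795 genes in the edgeR fit of sums over the 3 lines, 530 had an unadjusted p under 0.05. Because that fit shares the spread of all ligands, this count cannot tell whether genes changed. In that fit 0 genes passed, while DESeq2 gave 8 and a fit of these 2 groups alone gave 220. There the log2 difference was 1.45 for GREB1 (interval 0.20 to 2.69), −0.79 for MYC (−1.87 to 0.28) and −0.74 for MKI67 (−2.13 to 0.64). The estrogen-induced score was lower with GDC-0927 in 3 of 3 lines (difference −0.38, from −0.59 to −0.18; exact p = 0.25, the smallest that 3 lines allow).

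**Figure D3:**
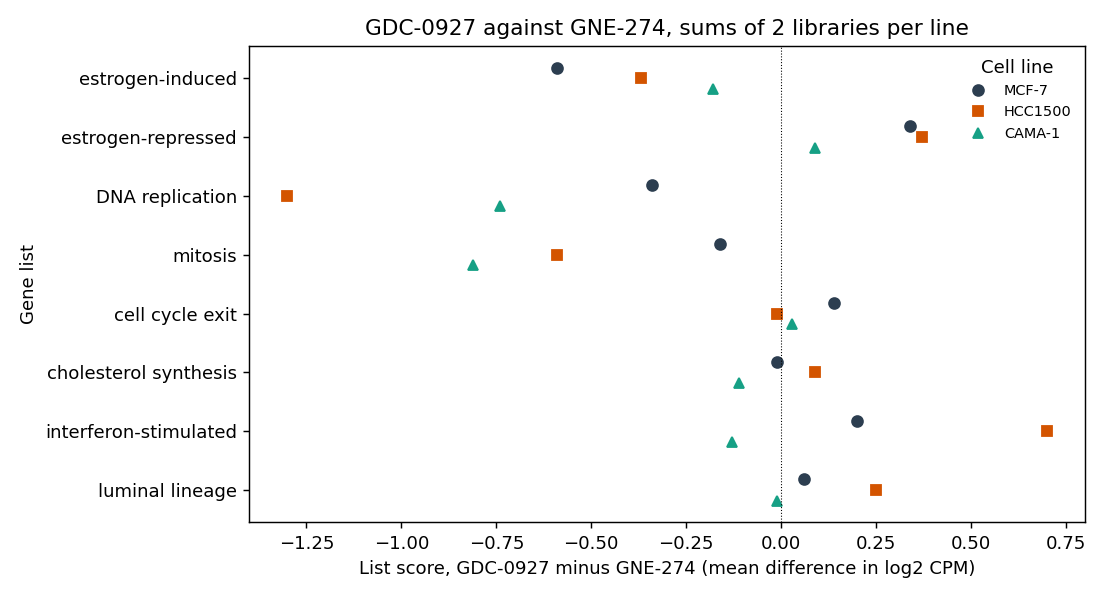
Mean difference in log2 CPM between GDC-0927 and GNE-274 (horizontal axis) for 8 gene lists (vertical axis), with a symbol for each of the 3 cell lines from the sum of its 2 libraries. The DNA replication list lies below 0 in all 3 lines, from −1.30 to −0.34.

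The positions of the main genes, on the GRCh38 build, are as follows. GREB1 (Entrez 9687) lies on chromosome 2 at 11534116 to 11642788, TFF1 (7031) on chromosome 21 at 42362282 to 42366535, and PGR (5241) on chromosome 11 at 101029624 to 101129813. KRT13 (3860) lies on chromosome 17 at 41500981 to 41505613, PGLYRP2 (114770) on chromosome 19 at 15468645 to 15479504, LINC01016 (100507584) on chromosome 6 at 33889511 to 33896907, and KIF12 (113220) on chromosome 9 at 114091623 to 114099320. PPM1K (152926) lies on chromosome 4 at 88257609 to 88284831, CYP1A1 (1543) on chromosome 15 at 74719542 to 74725610, and OAS1 (4938) on chromosome 12 at 112906934 to 112919907. LOC101930249, inside TFF1 on the opposite strand, rose with E2 by 4.29 log2 units and LOC101054525, which shares 101129077 to 101129813 with PGR on the opposite strand and otherwise lies outside it, by 3.18. Whether strand was used in counting is not stated, so reads in the stretches they share with TFF1 and PGR could not be assigned.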

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

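The tests of title blocks, of activity shared with Fulvestrant, of proportional agonism, of a line property behind the agonism of GDC-0810 and 4-OH tamoxifen, and all exchanges of ligands were chosen after the results were seen. The effect of each ligand differed between the lines by a test of the interaction: for 11129 genes with E2, 3706 with 4-OH tamoxifen, 3216 with GDC-0810 and 560 with Fulvestrant. Among estrogen-induced genes these were 45, 40, 43 and 32 of 45, and among DNA replication genes 30, 30, 30 and 26 of 30. GREB1 differed between lines with 4-OH tamoxifen (adjusted p = 1.29e-17), GDC-0810 (3.88e-13) and Fulvestrant (2.26e-16), from −3.02 log2 units in MCF-7 to 1.07 in MDA-MB-330 with GDC-0810. TFF1 (3.54e-12) and MYC (1.75e-10) differed with GDC-0810, PGR (5.52e-07) and CYP1A1 (0.00938) with Fulvestrant, and MKI67 with E2 (1.27e-19). Of 20 list scores examined over 7 lines, 4 had 1 line far from the others: mitosis in CAMA-1 with E2 (3.94) and 4-OH tamoxifen (1.45), estrogen-repressed genes in MCF-7 with Fulvestrant (0.56), and cholesterol synthesis in MDA-MB-330 with E2 (−0.08). Chance alone marks about 1 in 20 such groups.

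Many genes differed from DMSO with GDC-0927 and GNE-274 in MCF-7 and HCC1500, 9978 and 9116 with GDC-0927, against 28 in CAMA-1. Greater depth is argued against, since after thinning to 15.9 and 17.5 M counts GDC-0927 still called at least 4.23 times as many genes as Fulvestrant. Loss of receptor activity shared with Fulvestrant is argued against only as the whole cause, since GDC-0927 and Fulvestrant themselves differed in 8721 genes in MCF-7 and 9646 in HCC1500, at least 147.8 times as many as in CAMA-1. That comparison crosses title blocks in MCF-7 and HCC1500 and not in CAMA-1, so the multiple does not tell ligand from block, and a shared part stays open. A difference between title blocks stays open: the mean changes correlated across 12723 genes at r = 0.55 between MCF-7 and HCC1500, which cross blocks, and at most 0.08 with CAMA-1, a difference of 0.47, where Fulvestrant gave 0.04. A response that these lines share and CAMA-1 lacks was not tested, and the fall of interferon-stimulated genes in these lines may reflect either.

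For the rise of cholesterol synthesis genes with 4-OH tamoxifen, the expected value was a share of their E2 effect. The estrogen-induced score of each line gave that share. The rise exceeded the expected value by 0.17 ± 0.08 log2 units (SD) in 7 of 7 lines (exact 2-sided p = 0.0156, n = 7). This p is not adjusted over the lists. The 4-OH tamoxifen score of this list had the same p, with an adjusted p of 0.0832 over the lists. The test was chosen after that score was seen above 0 in 7 of 7 lines, and the expected value was at most 0.12. The excess thus largely repeats the rise. Its p cannot decide whether partial agonism in equal proportion is the whole cause. Without the 3 libraries with a high mitochondrial share the mean score was 0.22, against 0.21 with them, and above 0 in 7 of 7 lines. An effect of 4-OH tamoxifen on cholesterol synthesis apart from the receptor could explain the excess and was not tested.

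GDC-0810 lay above DMSO on the estrogen-induced list in some lines (0.71 in MDA-MB-330) and below in others (−0.98 in MCF-7). Against Fulvestrant, with no DMSO library, 80% of the list (36 of 45 genes) still differed between lines. DMSO libraries thus do not explain every difference between lines. The score difference from Fulvestrant ran from −0.09 in MCF-7 to 0.74 in MDA-MB-330 and cannot tell which lines lie above or below DMSO. Fulvestrant in MCF-7 (−0.90) lay nearly as far below DMSO as GDC-0810. The 2 DMSO libraries scored −0.01 and 0.01 in MCF-7 and 0.031 and −0.031 in MDA-MB-330. A single DMSO library apart is thus argued against in these lines, while a shift of both stays open. A property of the line that sets partial agonism for GDC-0810 and 4-OH tamoxifen alike could not be decided: the scores of 4-OH tamoxifen against DMSO and of GDC-0810 against Fulvestrant correlated at r = 0.71 (exact permutation p = 0.073, n = 7; Spearman rho = 0.61, exact permutation p = 0.167). Without MDA-MB-330 and MCF-7, the lines farthest out, r was 0.19 (exact permutation p = 0.8, n = 5). It was the only relation tested (1).

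Exchanging the ligands within lines gave 64 splits for each 7-line comparison, and in each 1 split, the real one, gave as many genes. That share is the smallest that 64 splits allow, and it is not adjusted over the 7 comparisons. It argues against chance, without excluding it, for the 5 comparisons other than GDC-0810 and Fulvestrant against DMSO. The 4 and 1 genes of the latter are too few to judge. The real count and the highest other were 9352 and 7045 for E2 (median of the others 8), 47 and 7 for 4-OH tamoxifen, 4 and 3 for GDC-0810, 1 and 0 for Fulvestrant, 42 and 2 for GDC-0810 against Fulvestrant, 105 and 17 for 4-OH tamoxifen against Fulvestrant, and 99 and 6 for GDC-0810 against 4-OH tamoxifen. The 4 splits of 3 lines are too few for a share under 0.05. Their real and highest other counts were 7 and 2 for GDC-0927, 20 and 12 for GNE-274, 0 and 1 for GDC-0927 against GNE-274, and 6 and 6 for GDC-0927 against Fulvestrant, with 1, 1, 4 and 2 splits as large.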

How the results depend on the processing

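The fits without 3 libraries with a high mitochondrial share and the count of genes called in each of 3 lines were chosen after the results were seen. No paired analysis was made because the labels give no replicate numbers. Most libraries that were not nearest to their duplicate were nearest to one with the same number in order of deposition. Examples are T-47D DMSO 1 with Fulvestrant 1 and BT-474 Fulvestrant 2 with DMSO 2. MDA-MB-330 Fulvestrant 1 and EFM-19 4-OH tamoxifen 2 went the other way. A fit with this number as a factor was not made. Where a library was left out within a line, the lone library was assumed to vary like the other groups. For the changes in counts below, the cause was not tested. Over 3 lines simulated changes of 0.5 log2 units were recovered in 16.4% of cases. BT-474 libraries, whose mitochondrial share was high throughout, stayed in the fits without 3 libraries, also where duplicates differed (6.18% and 10.7% with GDC-0810).

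The E2 counts over 7 lines (9352) and the interaction counts of E2 stayed within 1.5 times of their value under normalization, filter, DESeq2 and each line left out (E2 7634 to 9292 genes). The scores of E2, 4-OH tamoxifen and Fulvestrant kept their direction with size factors of DESeq2, a prior count of 0.5 and the median over members. With each line left out they ranged from 1.68 to 1.82, 0.37 to 0.48 and −0.39 to −0.24. The scores were not repeated without a filter or by the tests of DESeq2. Of 2205 repeats of 205 named gene values, 2201 kept their direction, 238 lost and 17 gained their call. Those that turned, none of which had passed, were ESR1 with E2 (from −0.26 to 0.03; 0.01 without MCF-7 and 0.03 without CAMA-1) and, without MCF-7, GREB1 with 4-OH tamoxifen (0.14; lowest −0.49 without MDA-MB-330) and GDC-0810 (0.30; lowest −0.43 without MDA-MB-330). Of 176 list tests, 55 lost their call with an estimated correlation.

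With size factors of DESeq2, GDC-0810 against DMSO gave 1 gene and Fulvestrant within MDA-MB-330 gave 26. Without a filter, GDC-0810 gave 2 and Fulvestrant 3. Within lines, 4-OH tamoxifen, GDC-0810 and Fulvestrant then gave 1190, 761 and 503 in EFM-19, 311, 217 and 398 in T-47D, and 1584, 1519 and 66 in BT-474. Fulvestrant gave 162 in MDA-MB-330 and 315 in CAMA-1, GDC-0927 gave 119 in CAMA-1, and the interaction counts of GDC-0810 and Fulvestrant were 5124 and 938. The Wald test of DESeq2 gave 81 genes for 4-OH tamoxifen, 13 for GDC-0810, 125 for GDC-0810 against Fulvestrant, 280 for GDC-0810 against 4-OH tamoxifen, 16 for GDC-0927, 114 for GNE-274, 8 for GDC-0927 against GNE-274 and 11 for GDC-0927 against Fulvestrant. Within lines it gave 7 for Fulvestrant in MDA-MB-330, 108 for GDC-0810 in T-47D, 451, 55 and 35 for 4-OH tamoxifen, GDC-0810 and Fulvestrant in BT-474, and 80 for Fulvestrant and 50 for GDC-0927 in CAMA-1. Its likelihood ratio test gave 906 for the Fulvestrant interaction.

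Single libraries, which count duplicates as independent, gave 322 for 4-OH tamoxifen, 207 for GDC-0810, 19 for Fulvestrant, 811, 1707 and 1727 for the comparisons of GDC-0810 with Fulvestrant, 4-OH tamoxifen with Fulvestrant and GDC-0810 with 4-OH tamoxifen, 6015 for GDC-0927, 5688 for GNE-274, 233 between these and 5386 for GDC-0927 against Fulvestrant. Fits of only the 2 groups gave 77, 37, 284, 293, 248 and 161 in the same order over 7 lines, and 3, 2 and 220 for GDC-0927, GNE-274 and their difference. Over 7 lines these held 23, 4, 1, 38, 75 and 59 of the 47, 4, 1, 42, 105 and 99 genes of the main fit. Without the high mitochondrial libraries GDC-0810 gave 1, and the interaction counts of 4-OH tamoxifen and Fulvestrant were 7142 and 1437. CAMA-1 alone gave 28 for GDC-0927, 2385 for GNE-274 and 59 for GDC-0927 against Fulvestrant, and 318 genes differed between GDC-0927 and GNE-274 in the same direction in 3 lines. The correlation of Fulvestrant with E2 was −0.70 among expressed genes.

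With 1 line left out at a time, counts ranged from 16 to 41 for 4-OH tamoxifen, 0 to 3 for GDC-0810, 0 to 2 for Fulvestrant, 14 to 30 for GDC-0810 against Fulvestrant, 49 to 89 for 4-OH tamoxifen against Fulvestrant, 32 to 107 for GDC-0810 against 4-OH tamoxifen, 1 to 3637 for GDC-0927, 0 to 2697 for GNE-274 and 0 to 2827 for GDC-0927 against Fulvestrant, with the highest of these last 3 without CAMA-1. Interaction counts were 1937 to 5174 for 4-OH tamoxifen, 1276 to 4251 for GDC-0810 and 217 to 1536 for Fulvestrant. The GDC-0810 score ranged from −0.15 to 0.13 (0.13 without MCF-7, 0.00 without EFM-19 and 0.01 without T-47D) and the GNE-274 score from −0.27 to 0.13 (without MCF-7).

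With 1 library left out, counts for 4-OH tamoxifen, GDC-0810 and Fulvestrant ranged from 186 to 219, 2040 to 2098 and 998 to 1153 in MCF-7, 2254 to 2611, 817 to 1593 and 313 to 373 in HCC1500, 492 to 577, 360 to 391 and 1 to 44 in MDA-MB-330, 47 to 6249, 108 to 128 and 5 to 14 in EFM-19, 38 to 185, 2 to 129 and 152 to 367 in T-47D, 25 to 37, 2 to 4546 and 11 to 14 in BT-474, and 1660 to 1910, 575 to 1232 and 4 to 505 in CAMA-1. E2 gave 4064 to 4360 in EFM-19, 3053 to 5791 in T-47D and 2480 to 2706 in BT-474. In CAMA-1 GDC-0927 gave 2 to 3 and GNE-274 1224 to 1746, and the pair differed in 857 to 1222 genes there and in 716 to 4900 in MCF-7.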

Other observations

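The test below was chosen after the result was seen, though its genes were chosen without any GNE-274 or GDC-0927 library. Genes that 4-OH tamoxifen raised over 7 lines may form a program that GNE-274 shares and GDC-0927 does not. Of the 43 genes, 42 were measured in the other fit, and 32 of them (76.2%) were higher with GNE-274 than GDC-0927 in each of MCF-7, HCC1500 and CAMA-1, with a median log2 difference of 0.81. Because 36 of the 42 were also higher with E2, 1000 sets of genes matched on their E2 response and expression were drawn for comparison. These held a median of 17 such genes and at most 27, and 0 sets held 32 or more. Across all 18795 genes 13.85% were higher with GNE-274 in all 3 lines. The change was larger with 4-OH tamoxifen than with E2 for 23 of the 42, for example KRT13 (4.27 and 2.57 log2 units), KIF12 (1.56 and 0.40) and IER3 (1.16 and 0.37), of which KIF12 and IER3 did not pass with E2. The genes were chosen for their rise with 4-OH tamoxifen in these libraries, which favors a larger change with it, so this count does not bear on a shared program. An agonist activity of GNE-274 that resembles that of tamoxifen is a candidate explanation. Against DMSO, however, the estrogen-induced score of GNE-274 was −0.62 in MCF-7, 0.06 in HCC1500 and 0.15 in CAMA-1. With 4-OH tamoxifen it was 0.12, 0.59 and 0.59. Only in CAMA-1 do GNE-274 and DMSO libraries share a title block. GREB1 and IGFBP4 went the other way, lower with GNE-274 than GDC-0927, so the higher expression with GNE-274 did not extend to all estrogen-induced genes. 4-OH tamoxifen itself lowered GREB1 below DMSO in MCF-7 (28.02 against 166 CPM), but not below Fulvestrant (22.8) or GDC-0810 (20.75). In HCC1500 GREB1 was at 29.03 CPM with 4-OH tamoxifen and 30.28 with Fulvestrant. Lower GREB1 with GNE-274 than GDC-0927 in MCF-7 thus does not show the resemblance. Matching within the same data and 3 lines leave the resemblance a hypothesis.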
